A study of Mus musculus with 4 samples.

How the data were processed

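RNA was measured in 4 libraries of EpH4 cells, a mouse mammary epithelial line grown in 2D culture, in 2 groups of 2: untreated control cells and cells treated with PM2.5, the fine fraction of airborne particulate matter. Per the labels' protocols, 750 ng of total RNA per library went into a stranded, ligation-based polyA library kit from Illumina. The labels give neither the dose of the particles nor the time of exposure, and they give a single batch value for all 4 libraries. They do not say that the replicates of a group were separate cultures, so the p-values measure the spread between these samples, which may be technical.

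Raw counts per gene were deposited by the authors without normalization, for 25413 genes, of which 7439 had 0 counts in every library. RPKM values, which scale each count to gene length and library size, were also deposited by the authors and came from the same counts, per the file headers. A further deposited count, named total gene reads in the file headers, was never below the raw count of the same gene, and the headers do not define the difference. Gene positions are on the GRCm39 build, which the submitters' processing notes name. The aligner, the counting program and the annotation release are not given in the sources used here. Whether counting used strand is likewise not given there, so reads of overlapping or antisense genes may not be separated, and near-identical copies such as pseudogenes can share reads.

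Total counts were 19562930 and 26206329 in the control libraries and 20232277 and 18548478 in the PM2.5 libraries. A count of 3, the floor used here for a gene at 0, corresponded to 0.116 to 0.158 CPM, counts scaled to library size, depending on the library. Intervals and floors cover counting error only, since reads without molecular identifiers are not independent molecules.

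The main comparison used edgeR 4.0.16 in R 4.3.3 on the raw counts of all 4 libraries. Genes were kept by filterByExpr, which left 12478, and library sizes were scaled by TMM, with factors of 0.973, 0.984, 1.02 and 1.024. The quasi-likelihood F test compared PM2.5 with control in an unpaired design, with Benjamini-Hochberg adjustment and a threshold of 0.05. Adjusted p-values in the text are from this test unless another is named. CPM values are TMM scaled and given as mean ± SD over 2 libraries. Log2 fold changes carry a standard error (SE) derived from the test, the absolute log2 fold change over the square root of F. For genes with few counts in a group, such as Vnn1, Chi3l1 and Kcnj15, this SE lies below counting error alone and understates the uncertainty. Gene lists, 31 in number, were fixed before the data were examined. The 28 lists with at least 5 tested members were tested as sets with camera (limma 3.58.1, preset correlation 0.01), with Benjamini-Hochberg adjustment over these lists. Ddit3 and Atp5po, members of the lists, were not analysed here.

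The genes named in the text followed a rule that was also fixed before the data were examined. It took genes past the threshold whose PM2.5 libraries both lay above or both below the control libraries, with a mean of at least 1 CPM and a symbol other than a predicted or clone name. Of these it took the 8 with the largest rise and the 8 with the largest fall on the log2 scale, and the 3 largest rises and 3 largest falls in CPM. It added up to 3 members of each list with the smallest p-values. Some genes that the rule took are not reported here. Genes named outside the rule are marked in the text as chosen after their values were seen.

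The calls were tested on simulated data made from the means and library sizes of these samples. Only 48 to 50 genes were changed at each fold, in both directions, and no chromosome region was shifted. The data had 39.6% of genes called and such shifts, so the rates below need not hold for those calls. In a step that kept 12336 genes, edgeR recovered 54.0% of genes changed 1.25-fold, 73.5% of those changed 1.5-fold, 91.7% of those changed 2-fold and 100% of those changed 4-fold, with 6 false calls among 163. DESeq2 recovered 44%, 65.3%, 87.5% and 96% of the same genes, with 0 false calls among 144.

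Alternatives fixed before the data were examined were other scalings (median-ratio factors, upper quartile, library size only), no filter and a stricter filter (1 CPM in 2 libraries and 50 counts in total), DESeq2 1.42.0, limma-voom, the legacy quasi-likelihood fit, a replicate block, leaving out each library, thinning every library to 18548478 counts, a minimum change of 1.5-fold, and limma-trend on log2(RPKM + 0.1) and log2(RPKM + 1). For the lists, camera with an estimated correlation and fry were added. With an estimated correlation, camera tests each list on the 2 residual degrees of freedom of the design. It then has little power, so a call lost there need not come from correlation between genes. A positional correction was added after the data were seen: each gene's fold change was set against the median of the 25 nearest genes above a log2 CPM of 3 on each side, and the model was refitted. A trend on GC content, exonic length and abundance was also fitted after the data were seen. Exonic lengths were recovered from the deposited counts and RPKM. GC content came from GENCODE M21 transcripts matched by gene identifier, and both values were found for 99.9% of the genes above that abundance.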

Results

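Transcript levels were measured in EpH4 cells, an immortalised mouse mammary epithelial line, in 2 untreated control libraries and 2 libraries from cells treated with PM2.5. The comparison asks which transcripts differ after exposure to fine particulate matter. Total counts ranged from 18548478 to 26206329 per library, and 17974 genes had counts in at least 1 library. Log2 CPM values correlated across genes at 0.9987 between the controls and 0.9988 between the PM2.5 libraries, against 0.9931 to 0.9948 between groups; genes are not independent replicates. Replicates differed by more than sampling noise, with a chi-square per gene of 7.22 in the controls and 3.79 in the PM2.5 libraries, more than 1 library deposited repeatedly would give; this spread may still be technical. Mitochondrial transcripts took 4.65% to 4.81% of the counts in the 4 libraries.

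PM2.5 libraries held more transcript of the vanin genes Vnn1 and Vnn3, of the secreted chitinase-like protein Chi3l1, of the interleukin 1 receptor antagonist Il1rn and of the acute-phase protein Saa3, and less of the protease inhibitor Timp3 and the coagulation inhibitor Tfpi. Of 12478 genes tested, 2399 were higher and 2540 lower in PM2.5 (edgeR quasi-likelihood test, adjusted p below 0.05), together 39.6% of the genes. Most changes were small: the median size among the 4939 called genes was 0.4 on the log2 scale. Changes of more than 2-fold were found in 574 higher and 146 lower genes. Without PM2.5 replicate 2 the count was 3110, with 1492 higher and 1618 lower, and a test against a minimum change of 1.5-fold called 401 higher and 112 lower. With scaling to library size only, the split was 3090 higher and 1889 lower, a share of 62.1% higher, and with DESeq2 the number higher was 1581.

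Vnn1, a pantetheinase (ENSMUSG00000037440, chromosome 10, 23770586 to 23781241, plus strand, GRCm39), had 0.24 ± 0.264 CPM in controls and 25 ± 1.52 CPM in PM2.5 (SD, n = 2 each), a log2 fold change of 6.52 (SE 0.266, edgeR adjusted p = 1.007e-07). The controls held 1 and 11 counts of Vnn1, and its log2 fold change was 5.85 without Control replicate 1. Without Control replicate 2 the control side rests on 1 count, under the floor of 3 counts, and no fold is given. Its family member Vnn3 (ENSMUSG00000020010, chromosome 10, 23727360 to 23745741, plus strand) went from 0.738 to 20.6 CPM. Chi3l1 (ENSMUSG00000064246, chromosome 1, 134109914 to 134117919) rose from 0.417 ± 0.0688 to 30 ± 3.7 CPM, a log2 fold change of 6.12 (SE 0.211). Il1rn rose from 0.6 to 19.6 CPM, 32.1-fold higher. The T cell receptor component Cd3g had 2 counts in the 2 controls together and 78 in the PM2.5 libraries, a ratio of 44.1 after scaling, with a 95% counting interval of 11.8 to 371. Tmsb4x, which encodes an actin-binding thymosin, rose from 0.313 to 7.51 CPM; it has near-identical copies, so its counts are uncertain. Stab1, a scavenger receptor, had a log2 fold change of 4.46 (SE 0.693) and the potassium channel gene Kcnj15 one of 4.40 (SE 0.396), each from under 10 control counts in total; for Stab1 it was 3.55 without PM2.5 replicate 1.

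Timp3 (ENSMUSG00000020044, chromosome 10, 86136236 to 86185370, plus strand), an inhibitor of matrix metalloproteinases, fell from 151 ± 2.69 to 22.4 ± 0.683 CPM, a log2 fold change of -2.75 (SE 0.067, edgeR adjusted p = 2.457e-09). Tfpi was 9.13-fold lower, at 34.6 CPM in controls and 3.77 CPM in PM2.5. Arhgap24 fell from 16.1 to 1.41 CPM and the phosphatase gene Ptpn13 from 7.36 to 0.653 CPM. They lie close together on chromosome 5, where Arhgap24 ends at position 103045803 and Ptpn13 starts at 103573058. Whether their falls are separate responses was not tested. Mpzl3 and Spsb4 had log2 fold changes of -3.85 (SE 0.474) and -3.33 (SE 0.508), with 5 and 8 counts in the PM2.5 libraries together. By absolute amount, the ferritin heavy chain Fth1 gained most, from 4449 ± 245 to 7761 ± 358 CPM. The matrix glycoprotein Thbs1 went from 907 ± 198 to 1795 ± 35.1 CPM and complement C3 from 544 ± 126 to 1414 ± 139 CPM. The largest falls in CPM were those of fibronectin, Fn1, from 4220 ± 617 to 2857 ± 342, of the chaperone gene Hsp90ab1, from 3840 ± 245 to 2820 ± 109, and of the translation elongation factor Eef1a1, from 9983 ± 11.7 to 8619 ± 120. The call on Eef1a1 (adjusted p = 0.0408) ended with either PM2.5 library left out and when scaled to library size only or by upper quartile.

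**Figure D1:**
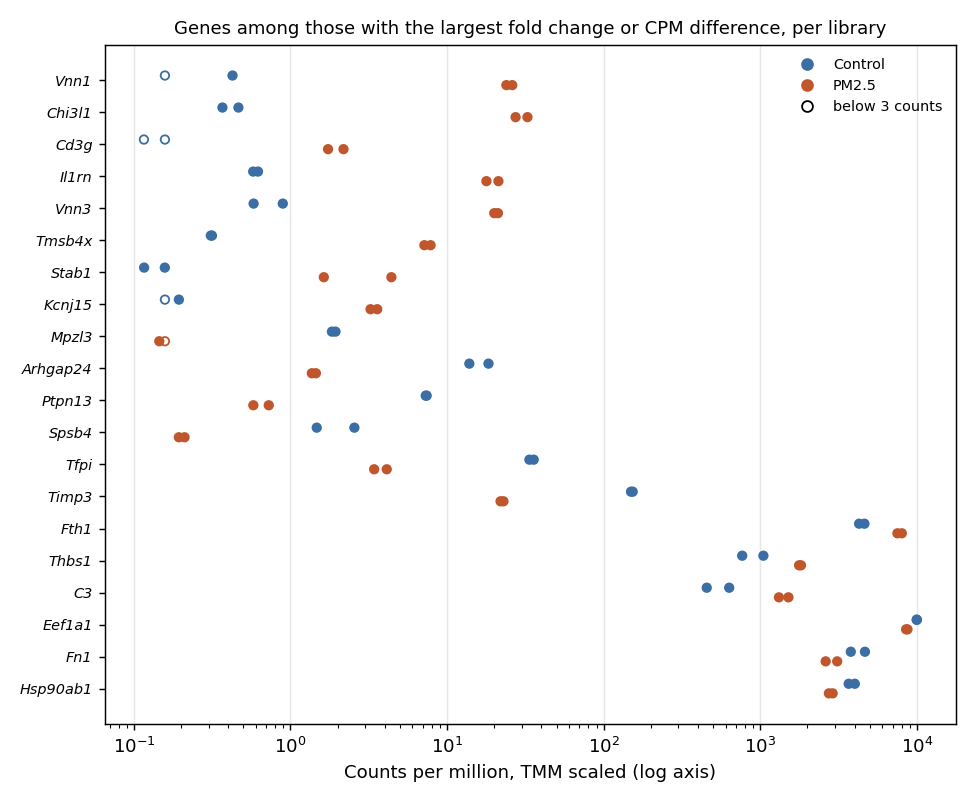
CPM (horizontal log axis, TMM scaled) of 20 genes among those with the largest fold changes or CPM differences (vertical axis), one point per library, blue for control and orange for PM2.5. Hollow points mark libraries below 3 counts, drawn at the level of 3 counts. Vnn1 lies at 25 CPM on average in PM2.5 and Timp3 at 22.4 CPM, against 0.24 and 151 CPM in controls.

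Targets of the aryl hydrocarbon receptor, the sensor of polycyclic aromatic and dioxin-like compounds, rose together. All 7 tested members of the list of 11 were higher in PM2.5, and all 7 were higher when adjusted over the list alone. The number called higher was 6 with DESeq2, with no filter and with the positional correction, and 5 with limma-trend on log2(RPKM + 1). Not all 7 stayed called without Control replicate 1 or with either PM2.5 library left out. Aldh3a1, an aldehyde dehydrogenase (ENSMUSG00000019102, chromosome 11, 61098363 to 61109247), rose from 25.9 ± 2.29 to 183 ± 8.43 CPM, a log2 fold change of 2.83 (SE 0.076, adjusted p = 4.853e-09). Cyp1b1, a cytochrome P450, rose from 4.06 ± 0.238 to 20.3 ± 0.516 CPM, and Tiparp, a feedback regulator of the receptor, from 60.3 to 112 CPM. The other 4 were Nqo1 and the glucuronosyltransferases Ugt1a6a, Ugt1a6b and Ugt1a7c, named after their values were seen where outside the rule; the Ugt1a genes overlap one another, so their counts are uncertain. Cyp1a1 had 0 counts in 3 libraries and 0.105 CPM in PM2.5 replicate 2, and was not tested. The list moved up as a set (camera adjusted p = 1.03e-14), and fry gave adjusted p = 0.013. With an estimated correlation camera gave adjusted p = 0.39. The estimate for this list was -0.085, below the preset 0.01, so correlation between genes does not account for that loss.

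The antioxidant targets of NRF2 went both ways: 4 of 28 tested members were higher and 10 lower, and 4 and 13 when adjusted over the list alone. Nqo1, a quinone reductase also on the aryl hydrocarbon receptor list, rose from 29.5 to 52.1 CPM, and Fth1 rose 1.74-fold. The transporter Abcc1 fell from 207 to 153 CPM, and its call ended with the positional correction described with the chromosome medians below (log2 fold change -0.09, adjusted p = 0.26). The set test did not call the list (adjusted p = 0.273), and without PM2.5 replicate 2 the number lower was 5. In the metal response list, 2 of 10 were higher and 3 lower over all genes and adjusted over the list alone (set test adjusted p = 0.882). With either PM2.5 library left out, 1 was higher. The transferrin receptor Tfrc fell from 359 ± 0.501 to 230 ± 33.5 CPM while Fth1 rose. With the positional correction the log2 fold change of Tfrc went from -0.64 to -0.34 and that of Fth1 from 0.8 to 0.62. Both calls stayed. The metal-responsive factor Mtf1 had a log2 fold change of -0.26 (adjusted p = 0.0167), and that call ended with DESeq2, library size only, limma-trend on RPKM, the positional correction and without PM2.5 replicate 2, where 1 member was lower.

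Among NF-kB and cytokine genes, 12 of 25 tested members were higher and 5 lower, with the same counts when adjusted over the list alone. Saa3 rose from 85.2 ± 24.6 to 728 ± 29.4 CPM, the chemokine gene Cx3cl1 from 67.2 ± 4.67 to 247 ± 7.48 CPM and Tnfaip3, a negative regulator of NF-kB, from 20.6 ± 3.23 to 79.8 ± 2.18 CPM. The growth factor gene Csf3, from 0.593 to 8.54 CPM, and the siderophore-binding Lcn2, from 349 to 790 CPM, were higher too. The 5 lower members were the chemokines Cxcl5, Ccl5 and Ccl7, the cytokine Tslp and the regulator Nfkbiz; these and the preceding pair were chosen after their values were seen. The list moved up as a set (camera adjusted p = 1.16e-06; adjusted p = 0.41 with an estimated correlation). Of 34 interferon-stimulated genes, 17 were higher and 2 lower, and 19 and 2 when adjusted over the list alone. The guanylate-binding protein genes Gbp2 and Gbp3 rose from 39.4 to 102 CPM and from 7 to 22 CPM. The lower members were Isg15 and Trim25, chosen after their values were seen; both calls ended with the positional correction. The number lower was 1 when Control replicate 2 or either PM2.5 library was left out. The interferon list moved up as a set (camera adjusted p = 4.53e-04; adjusted p = 0.62 with an estimated correlation).

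Matrix proteases and their inhibitors changed in both directions, with 11 of 23 tested members higher and 5 lower over all genes and adjusted over the list alone (set test adjusted p = 0.21). The gelatinase Mmp9 rose from 30.1 ± 0.546 to 109 ± 12.2 CPM and the cathepsin Ctsl from 359 ± 16.1 to 735 ± 24.5 CPM, while Timp3 fell. In the lysosome and autophagy list, 11 of 29 were higher and 5 lower over all genes and adjusted over the list alone. Without PM2.5 replicate 2 the number lower was 2. Ctsl and Ctsb (342 to 570 CPM), both lysosomal hydrolases, were among the higher members. Endoplasmic reticulum chaperones and stress genes were higher in 11 of 20 and lower in 2, and in 11 and 3 when adjusted over the list alone; without PM2.5 replicate 1 or 2 the number higher was 7 or 6. The number lower was 1 without Control replicate 1 or with either PM2.5 library left out. Dnajc3 rose from 107 to 152 CPM and Manf from 84.4 to 118 CPM. The translocon subunit Sec61b fell from 92.4 to 62.7 CPM, a call that ended with the positional correction. Neither the lysosome list nor the endoplasmic reticulum list was called as a set (adjusted p = 0.07 for each), but with the positional correction both were, at adjusted p = 0.0164 and 0.00177. With an estimated correlation and all 4 libraries they had adjusted p = 0.82 and 0.7. Scaling to library size only also called both, at 0.0475 and 0.0425, as did leaving out Control replicate 2 for the lysosome list (0.012) and Control replicate 1 for the other (0.0389).

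Transcripts of cytosolic ribosomal proteins were lower in PM2.5 in 47 of 52 members and higher in 0, and lower in 49 when adjusted over the list alone. Rpl24 fell from 574 ± 13.6 to 374 ± 8.14 CPM, Rps20 from 1034 ± 19.8 to 690 ± 13.2 CPM and Rps6 from 2048 ± 52.7 to 1373 ± 3.65 CPM. Rpl24 lies on chromosome 16 and Rps20 and Rps6 on proximal chromosome 4, regions lowered in PM2.5. With the positional correction their log2 fold changes went from -0.62, -0.58 and -0.58 to -0.34, -0.18 and -0.33. Their calls stayed, and 44 members of the list were lower. The median log2 fold change of the list was -0.3, and it was -0.10 once a trend on GC content, exonic length and abundance was removed. Ribosomal protein genes have processed pseudogenes, so their counts carry that uncertainty. The list moved down as a set (camera adjusted p = 1.03e-14; adjusted p = 0.41 with an estimated correlation; fry adjusted p = 0.013). The number lower was 31 without PM2.5 replicate 1 and 30 without PM2.5 replicate 2. With scaling to library size only it was 39.

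Heat shock genes were lower in 9 of 15 and higher in 1, Hspa4l, chosen after its value was seen, and lower in 12 when adjusted over the list alone. The co-chaperones Dnaja1 and Dnajb1 fell from 331 to 210 CPM and from 66.9 to 49.9 CPM. The set test called the list down (adjusted p = 0.0033; adjusted p = 0.7 with an estimated correlation), and the call on Dnaja1 ended with the positional correction. The median log2 fold change of the heat shock list was -0.29, and -0.17 after removal of the trend on GC content, length and abundance. Of 22 targets of the integrated stress response factor ATF4, 9 were lower and 2 higher over all genes and adjusted over the list alone. Asns, asparagine synthetase, fell from 142 to 96.9 CPM, the amino acid transporter Slc7a5 from 295 to 172 CPM and the alanyl-tRNA synthetase Aars1 from 477 to 318 CPM. As a set, this list was called down (adjusted p = 0.0367; adjusted p = 0.62 with an estimated correlation), a call that ended without PM2.5 replicate 2 (adjusted p = 0.0617). The call on Aars1 ended with the positional correction (log2 fold change -0.16, adjusted p = 0.0689). That on Slc7a5 stayed, with its log2 fold change going from -0.78 to -0.43.

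Genes of S phase and DNA replication were lower in 12 of 30 and higher in 0, and lower in 15 when adjusted over the list alone. The licensing factor Cdt1 fell from 150 to 110 CPM, the helicase subunit Mcm4 from 271 to 198 CPM and the histone chaperone subunit Chaf1a from 160 to 126 CPM. The list was called down as a set (adjusted p = 0.0338; adjusted p = 0.82 with an estimated correlation), but not without Control replicate 1 (adjusted p = 0.125). The number lower was 7 with either PM2.5 library left out. With scaling to library size only 4 were higher and 9 lower, with upper quartile 3 and 9, and without Control replicate 1, 2 and 8. The median log2 fold change of the S phase list was -0.17, and -0.07 after removal of the trend on GC content, length and abundance. Its estimated correlation was 0.379, well above the preset 0.01, so correlation between its genes may undo the set call. With the positional correction 3 members were lower, the calls on Cdt1, Mcm4 and Chaf1a ended, and the set test gave adjusted p = 0.0768. Nuclear-encoded subunits of the respiratory chain were lower in 12 of 36 and higher in 1 over all genes and when adjusted over the list alone. The higher member was Sdha, chosen after its value was seen, and its call ended with the positional correction and when Control replicate 2 or either PM2.5 library was left out. Ndufa8 fell from 45.6 to 27.9 CPM, Atp5f1c from 256 to 195 CPM and Cox4i1 from 255 to 193 CPM, the last of these only without the positional correction. The respiratory list was called down as a set (adjusted p = 0.0294; adjusted p = 0.82 with an estimated correlation), a call that ended without Control replicate 1 (adjusted p = 0.0557) or PM2.5 replicate 2 (adjusted p = 0.0766), where 6 were lower. Its median log2 fold change was -0.1, and 0.07 after removal of the GC, length and abundance trend. The estimated correlation of the respiratory list was 0.276, well above the preset 0.01, so here too correlation may undo the set call. Of 13 mitochondrially encoded mRNAs, mt-Nd1, mt-Nd2 and mt-Nd3 were lower and 0 higher over all genes and adjusted over the list alone (set test adjusted p = 0.236), and 1 was lower with either PM2.5 library left out. With scaling to library size only, 2 of the 13 were higher, and with DESeq2, limma-voom or no filter 5 were lower.

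**Figure D2:**
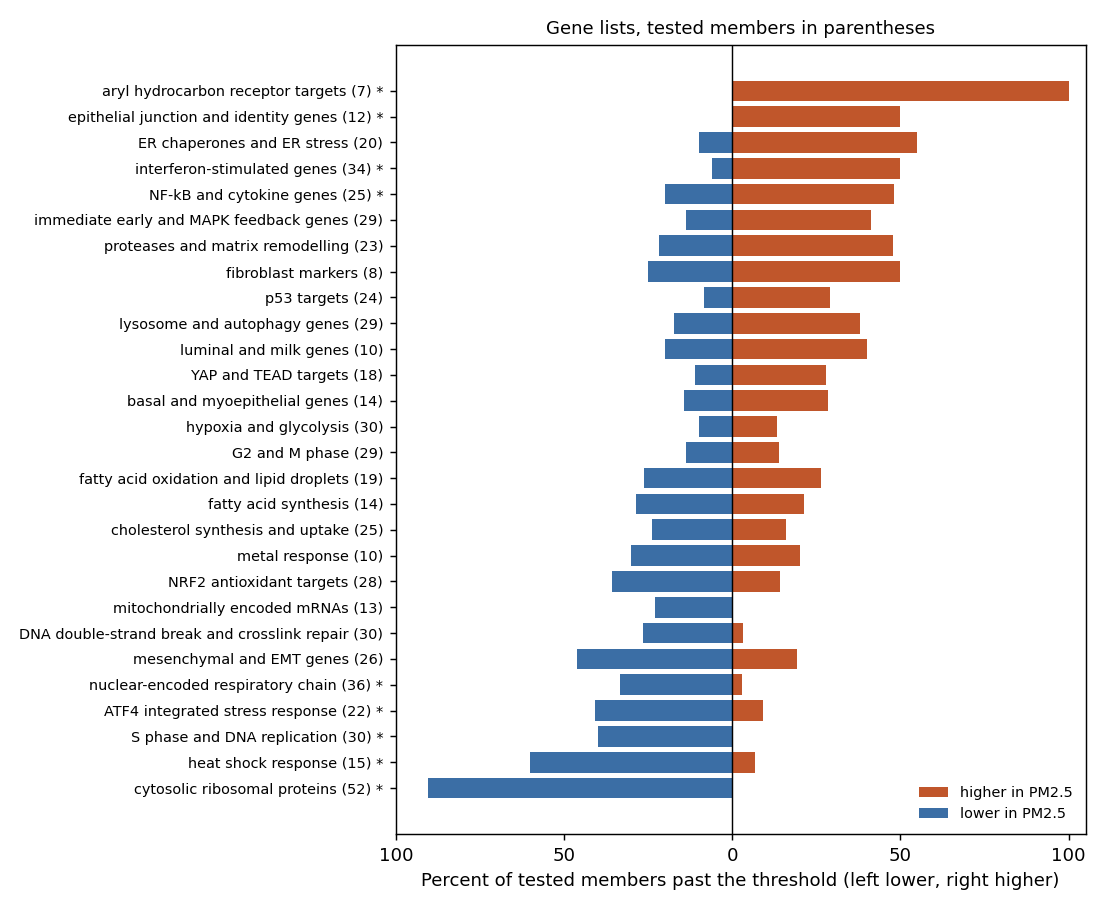
Percent of each list's tested members (number in parentheses) that were higher (orange, right) or lower (blue, left) in PM2.5 at adjusted p below 0.05, with lists ordered by the difference of these shares. A star marks the 9 lists called by camera at a preset correlation of 0.01. With an estimated correlation, where camera tests on 2 residual degrees of freedom, 0 lists were called. Aryl hydrocarbon receptor targets lie at 7 of 7 higher and ribosomal proteins at 47 of 52 lower.

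Several transcripts typical of epithelial cells were near 0 in all 4 libraries. Of 30 epithelial junction and identity genes, 21 had a mean below 1 CPM and 12 were tested. The cadherin Cdh1 had 0.118 ± 0.0567 CPM in controls and 0.15 ± 0.0626 CPM in PM2.5, and Epcam, Cldn4 and Esrp1 had 0 counts in every library, below 0.116 to 0.158 CPM. The keratins Krt18, Krt19 and Krt5 were also at 0. Among the 12 tested, 6 were higher in PM2.5 and 0 lower over all genes and adjusted over the list alone. The junction proteins Jup and Pkp1 rose from 1.71 to 4.6 CPM and from 1.42 to 2.96 CPM. The set test called the list up (adjusted p = 0.0394; adjusted p = 0.62 with an estimated correlation), a call that ended with the positional correction (adjusted p = 0.0768, with a list median of 0.42 against 0.40 before and 6 members higher both times), without Control replicate 1 (adjusted p = 0.0557) and without PM2.5 replicate 2 (adjusted p = 0.0617). The genes at 0 and their values were singled out after they were seen.

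Mesenchymal transcripts were abundant in both groups, and 12 of 26 tested members of that list were lower and 5 higher, or 12 and 6 when adjusted over the list alone (set test adjusted p = 0.07). The set test called it down without Control replicate 1, Control replicate 2 or PM2.5 replicate 2, at adjusted p = 0.0151, 0.0147 and 0.0424. With an estimated correlation and all 4 libraries it had adjusted p = 0.7. Periostin, Postn, fell from 150 ± 18.8 to 66.4 ± 4.28 CPM and the transcription factor Prrx1 from 213 ± 24.5 to 121 ± 0.457 CPM, while the growth factor Tgfb1 rose from 47.2 to 84.7 CPM. Vimentin, Vim, named after its value was seen, was at 2197 ± 44 CPM in controls and 1470 ± 29.4 CPM in PM2.5. Of 8 tested fibroblast markers, 4 were higher and 2 lower, or 4 and 3 when adjusted over the list alone (set test adjusted p = 0.287, and 0.0369 without PM2.5 replicate 1, where 1 was lower). With an estimated correlation and all 4 libraries the fibroblast list had adjusted p = 0.83. Decorin, Dcn, rose from 63.9 ± 28 to 251 ± 42 CPM and the collagen Col3a1 from 2.62 to 8.26 CPM, and the receptor Pdgfrb fell from 234 to 165 CPM. Basal and myoepithelial genes were higher in 4 of 14 and lower in 2, or 5 and 2 adjusted over the list alone (set test adjusted p = 0.915). Keratin 14, Krt14, fell from 52 ± 1.43 to 19.7 ± 1.52 CPM and the cadherin Cdh3 from 2.66 to 0.407 CPM, and the kinase Mylk rose from 26.9 to 44.1 CPM. Of 10 tested luminal and milk genes, 4 were higher and 2 lower over all genes and adjusted over the list alone (set test adjusted p = 0.743), with Mfge8 up from 161 to 190.0 CPM. Without PM2.5 replicate 2 the number higher was 2 in the basal and in the luminal list, and in the basal list also without Control replicate 1. In the luminal list 0 were lower without PM2.5 replicate 1 and with scaling to library size only, and 1 without Control replicate 2 or PM2.5 replicate 2. The median log2 fold change of the basal list was 0.39, and -0.10 after removal of the trend on GC content, length and abundance.

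**Figure D3:**
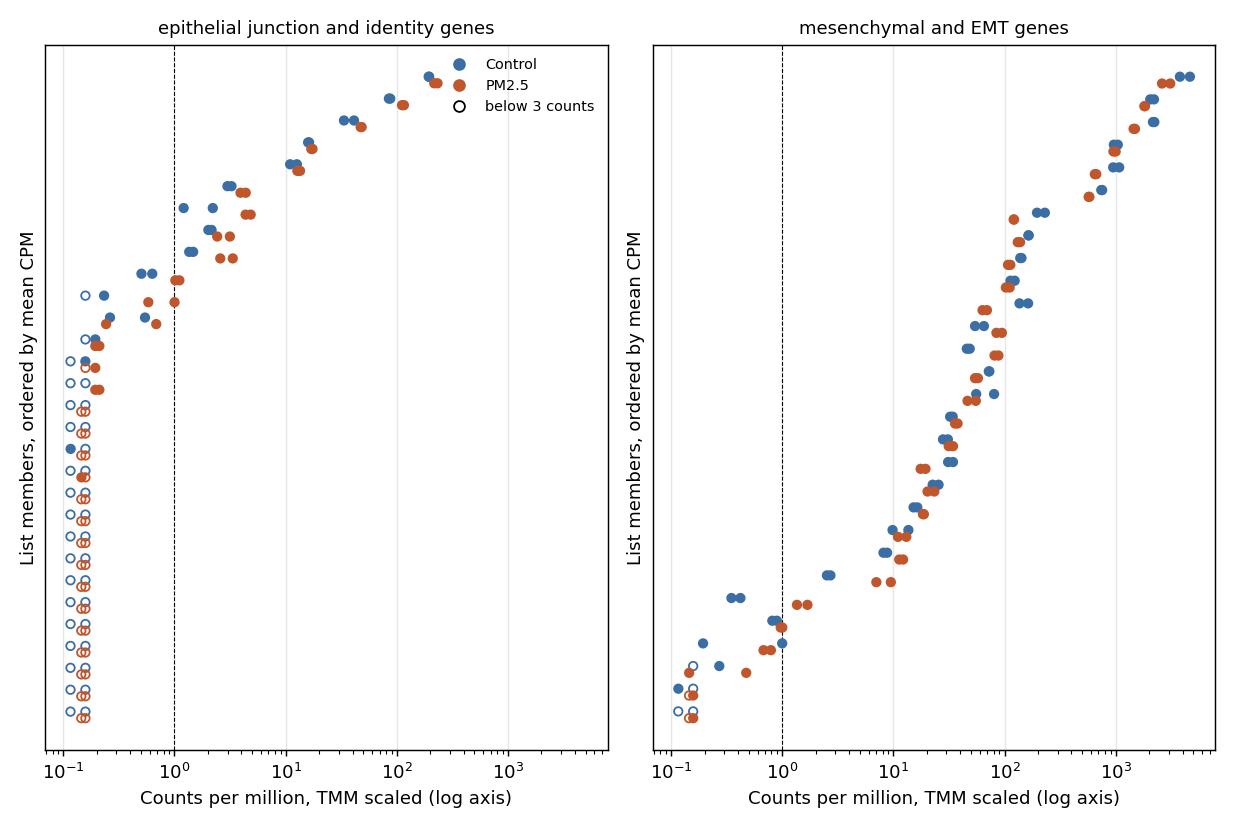
CPM (horizontal log axis, TMM scaled) of the members of the epithelial and the mesenchymal list (vertical axis, each list ordered by mean CPM), one point per library, blue for control and orange for PM2.5, hollow points below 3 counts and drawn at that level; the dashed line marks 1 CPM. Of the 30 epithelial genes 21 lie below the line on average, and 22 of the 29 mesenchymal genes lie at 10 CPM or more.

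Lists of markers of other cell types had few tested members. In the endothelial list 3 of 9 genes were tested and Flt1 was higher, at 0.998 and 1.95 CPM, a call that ended when Control replicate 2 or either PM2.5 library was left out, and with DESeq2 and limma-trend on RPKM. In the immune list 2 of 11 were tested, and Cd68, a macrophage and lysosome marker, rose from 3.93 to 9.67 CPM. In the adipocyte list 2 of 8 were tested: the fatty acid-binding protein gene Fabp4 rose from 0.443 to 4.84 CPM and Pparg fell from 1.5 to 0.301 CPM. These counts were the same when adjusted over the list alone. These lists had fewer than 5 tested members and were not tested as sets.

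The remaining lists were not called as sets. Immediate early and MAPK feedback genes were higher in 12 of 29 and lower in 4, or 14 and 4 adjusted over the list alone (adjusted p = 0.236). Phlda1 rose from 82.4 to 168 CPM and Ier3 from 38 to 54 CPM, and the transcription factor Jun fell from 141 ± 8.81 to 77.5 ± 0.815 CPM. Among p53 targets 7 of 24 were higher and 2 lower over all genes and adjusted over the list alone (adjusted p = 0.242). Without PM2.5 replicate 1 the number higher was 4, and without Control replicate 2 the number lower was 5, and 1 without PM2.5 replicate 2. The death receptor Fas rose from 15.9 to 42.5 CPM and the cell cycle inhibitor Cdkn1a from 106 to 147 CPM. Of 30 genes of double-strand break and crosslink repair, 8 were lower and 1 higher, or 7 and 1 adjusted over the list alone (adjusted p = 0.191), with Nbn down from 52 to 31.5 CPM. With either PM2.5 library left out 5 were lower and 0 higher. With the positional correction 1 was lower, and the calls on Rad50 and Fanca ended.

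In the cholesterol list 4 of 25 were higher and 6 lower (adjusted p = 0.704), with a median log2 fold change of 0.04, a mean of -0.11 and a set test pointing down. The number higher was 1 without Control replicate 1 or PM2.5 replicate 2 and 8 without Control replicate 2, and the number lower was 3 without PM2.5 replicate 1. Stard4 fell from 122 to 94.9 CPM and Sc5d rose from 127 to 160 CPM. Fatty acid synthesis genes were higher in 3 of 14 and lower in 4 (set test adjusted p = 0.637), with the regulator Srebf1 down from 132 to 84.1 CPM. The number higher in this list was 1 with DESeq2, no filter, thinning and the positional correction. It also dropped without PM2.5 replicate 2. Genes of fatty acid oxidation and lipid droplets were higher in 5 of 19 and lower in 5 (adjusted p = 0.805), or 6 and 6 adjusted over the list alone; their median was -0.03 and their mean 0.2. Without PM2.5 replicate 1 the counts were 3 and 3. Pdk4 rose from 8.11 to 16.6 CPM, and Ehhadh had 3 control counts and 44 in PM2.5, a ratio of 16.6 with a 95% counting interval of 5.32 to 83.5. G2 and M phase genes were higher in 4 of 29 and lower in 4, or 3 and 3 adjusted over the list alone (adjusted p = 0.951). With library size only, 9 were higher and 1 lower. Without PM2.5 replicate 2, 1 was higher and 1 lower, and without Control replicate 2, 2 were lower. In this list the calls on Cdc20, Kif11 and Aurka ended with the positional correction. YAP and TEAD targets were higher in 5 of 18 and lower in 2, or 4 and 2 adjusted over the list alone (adjusted p = 0.606), with the ectonucleotidase Nt5e up from 43.9 to 87.1 CPM. The number higher was 9 without Control replicate 1 and 3 without any 1 of the other libraries. Without Control replicate 2 the number lower was 5 and the set test pointed down (adjusted p = 0.815), and without Control replicate 1 or PM2.5 replicate 2 the number lower was 1. Hypoxia and glycolysis genes were higher in 4 of 30 and lower in 3, or 4 and 2 adjusted over the list alone (adjusted p = 0.738). Without Control replicate 2 the number higher was 14 and the list was called up. With an estimated correlation and all 4 libraries it had adjusted p = 0.93. Without Control replicate 1 the set test pointed down (adjusted p = 0.121), and the number lower was 9, and 1 without PM2.5 replicate 1. The counts of the cholesterol and fatty acid synthesis lists were the same when adjusted over the list alone.

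Fold changes also differed by chromosome. Over 9666 nuclear genes above a log2 CPM of 3, the median log2 fold change was -0.28 on chromosome 16, -0.25 on chromosome 4, -0.17 on chromosome 8 and 0.17 on chromosomes 14 and 19. Between the libraries of a group, the SD of the 20 chromosome medians was 0.015 in controls and 0.009 in PM2.5, against 0.124 between the groups. On chromosome 8 the median was -0.01 for 264 genes before position 84156713 and -0.35 for 279 genes after it (permutation test of gene order, adjusted p = 0.005, from the smallest p that 1000 permutations can give). On chromosome 4 it was -0.45 for 267 genes before position 108918342 and -0.12 for 337 genes after it (permutation test, adjusted p = 0.005). A change point was called on 9 of 20 chromosomes, with steps of 0.34 on chromosome 8 and 0.33 on chromosome 4. On the other called chromosomes the steps were smaller, from 0.07 on chromosome 12 to 0.21 on chromosome 2. With the positional correction 3863 genes were called, 2280 higher and 1583 lower, a share of 59.0% higher. Of the 4939 genes called without it, 3226 kept their call and direction and 233 had the opposite sign. Genes are not independent replicates.

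**Figure D4:**
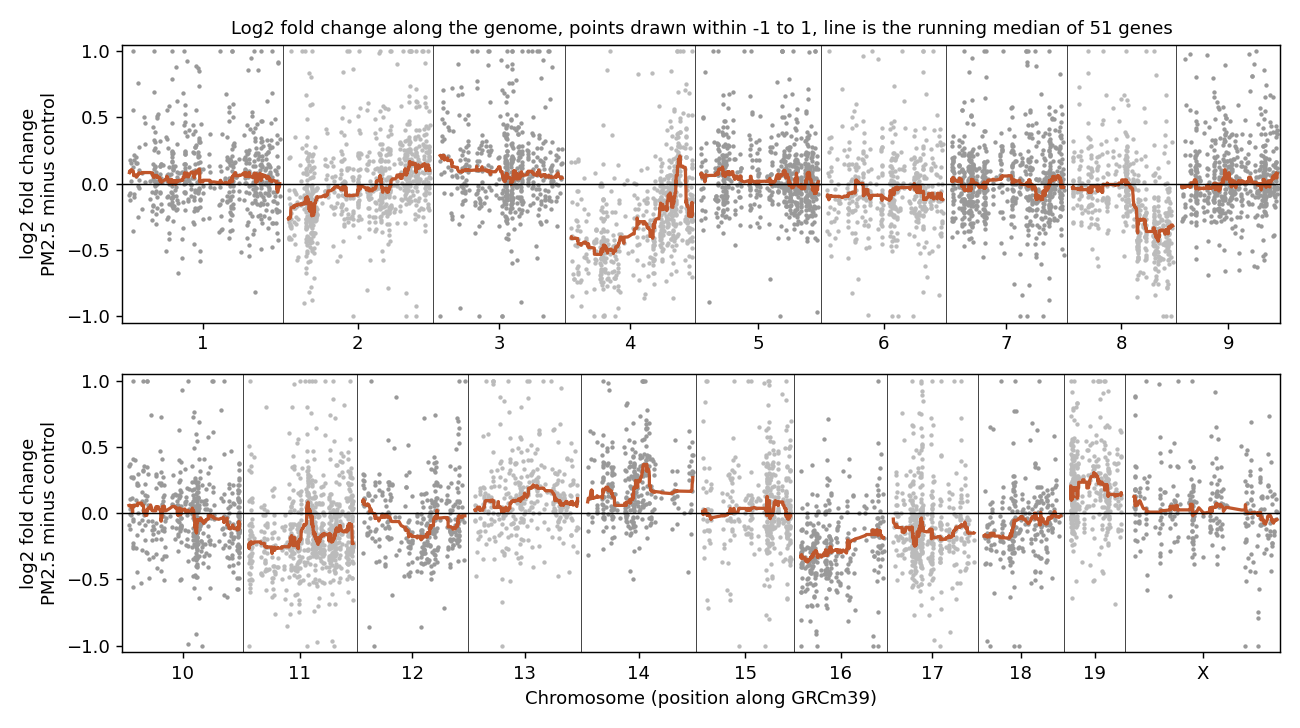
Log2 fold change of PM2.5 over control (vertical axis, points beyond -1 or 1 drawn at those values) against position on GRCm39 (horizontal axis, chromosomes 1 to 19 and X) for genes above a log2 CPM of 3. The orange line is the running median of 51 genes. It steps down within chromosome 8, from a median of -0.01 to -0.35, and lies below 0 along chromosome 16, at a median of -0.28.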

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

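The share of gene reads outside the counted total, which the comparisons above do not use, was higher in the PM2.5 libraries than in the controls. It was 9.81% and 10.53% in the controls and 11.66% and 11.59% in the PM2.5 libraries, means of 10.17 ± 0.51% and 11.62 ± 0.05% (SD, n = 2 each). In 15673 genes whose span exceeds their exonic length the share was 10.52% in controls and 12% in PM2.5, and in 2301 genes without introns it was 2.86% and 3.09%. With 2 libraries against 2, an exact permutation test cannot reach a p below 0.05, so none was run.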

How the results depend on the processing

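The positional correction and the trend on GC content, length and abundance were chosen after seeing the data; the other alternatives were not. The count of changed genes was 513 against a minimum of 1.5-fold (401 higher, 112 lower), which follows from the stricter hypothesis. Leaving out each library in turn gave 3110 to 4842 changed genes, 1492 to 2267 higher and 1618 to 2575 lower, with the lowest values without PM2.5 replicate 2; the lone library of a group is then assumed to vary like the other group's. DESeq2 called 1581 higher, and the positional correction called 1583 lower; the cause of the first was not tested. Of gene lists moved as a set, 9 in the main test, fry called 2, and fry's test for change in either direction called 27 of 28. Camera with an estimated correlation called 0 (3 at an unadjusted p below 0.05). That setting tests on 2 residual degrees of freedom, so a call lost there need not come from correlation between genes. The estimated correlations, from 4 libraries, were 0.427 for heat shock, 0.379 for S phase and 0.276 for the respiratory list. These lie well above the preset 0.01, so correlation may undo those calls. In the other called lists the estimates ran from -0.085 to 0.075. Leaving out each library gave 7 to 12 lists. The remaining alternatives gave 3509 to 5793 changed genes. No called gene changed sign under any alternative fixed before the data were examined. Of 106 named genes, 11 lost the threshold in at least 1 of these, the 1.5-fold minimum left aside, and 17 with the positional correction; Lyz2 passed it in both RPKM fits. The labels do not say whether the replicate numbers 1 and 2 mark a shared culture or day, so a pairing of same-numbered libraries stays open. A replicate block leaves 1 residual degree of freedom. A fit with the replicate block called 5793 genes and 11 lists, the added ones being the mesenchymal list (adjusted p = 0.0227) and the lysosome list (adjusted p = 0.0488), and the deviations of same-numbered libraries correlated at 0.28 over 9680 genes. Depth limits genes below a few counts, whose folds rest on counting error, as for Cd3g and Ehhadh.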

Other observations

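The tests of scatter between libraries, of segments for ribosomal proteins, of reads lost between the deposited counts and of mesenchymal transcripts were chosen only after the result was seen, and the positional correction was chosen after seeing the data.

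The genes in this paragraph lie outside the rule for naming and were chosen after their values were seen. The collagenase Mmp13 went from 0.19 to 2.64 CPM (log2 fold change 3.83, SE 0.451), the urokinase gene Plau from 3.69 to 13.0 CPM and dermatopontin, Dpt, from 1.1 to 3.76 CPM. The protease Adamts1 fell from 172 ± 27.4 to 53.6 ± 5.37 CPM. Immediate early gene Egr1 went from 0.222 to 1.27 CPM, and Spry4, an inhibitor of receptor tyrosine kinase signalling, from 0.0914 to 0.708 CPM, both at low counts.

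Chromosome segments shifted between the groups. Removing a smooth trend on GC content, exonic length and abundance left a step of 0.32 on chromosome 8, so such a trend does not account for it. Chromosome medians varied 8.3 times as much between groups as between libraries of a group, which argues against scatter between libraries. Genes of low, middle and high abundance on chromosome 16 and on distal chromosome 8, segments picked because they were lowered, all had medians of -0.24 or lower, and those on proximal chromosome 4, added later, had medians of -0.41, -0.46 and -0.51. As that choice nearly fixed the outcome, a copy number difference between the cells of the 2 groups stays open, and whether one came with the treatment or existed between sub-cultures is confounded with the groups.

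Ribosomal protein genes were lower in PM2.5. In total gene reads, which hold the uncounted reads, their median log2 fold change was -0.32 (SD 0.13 over 52 genes), which argues against reads that left the counted total. With the positional correction it was -0.25 (SD 0.09), which argues against chromosome segments as the whole cause. After removal of the trend on GC content, length and abundance it was -0.10 (SD 0.13), so a technical trend and a change in these transcripts cannot be told apart: these genes are short, with a median exonic length of 1133 bases against 3418 over the tested genes. A fall of ribosomal protein transcripts with the treatment may therefore be partly a trend of the libraries.

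Epithelial genes were near 0 in every library. Of the 21 list members under 1 CPM, 2 reached 1 CPM in total gene reads, so reads lost between total gene reads and counts do not account for the low values. Reads missing from both, as from genes with near-identical copies, were not tested and stay open. Of the mesenchymal list 75.9% of members were at 10 CPM or more, against 16.7% of the epithelial list, consistent with cells that carry a mesenchymal set of transcripts in both groups, as a hypothesis. Whether the line had changed in culture or cells of another kind were present stays open.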
